A study of Mus musculus with 10 samples.

How the data were processed

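Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in mouse embryonic stem cells of the R1E line, either untreated or exposed to 0.5 uM Adriamycin for 8 h. Adriamycin (doxorubicin) poisons topoisomerase II and breaks DNA. The 5 targets were trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active and poised promoters, H3K27me3, the mark of Polycomb repression, H3K79me2, a mark of transcribed gene bodies, RNA polymerase II (Pol II), and hnRNP L, an RNA-binding protein. Each target had 1 library per condition, 10 libraries in all.

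Each library was used as a list of peaks that the authors deposited. Per the submitters' processing notes, the software named was CASAVA 1.8.2 and MACS 1.4.1 and the genome build was mm9. The deposited peak lists give a chromosome, a start, an end, a name and a score for each peak. MACS of this generation writes as its score 10 times the negative log10 of the peak's p-value, so the lowest deposited score of 50 corresponds to a p of 1e-05. The score is the authors' value and was used here to rank and filter peaks within a list. Scores of 3100 and above were treated as the ceiling of the scale. Read depth, use of an input library and treatment of duplicate reads are not given in the sources used here, so the sensitivity of each library is unknown. Peaks were called separately for each library, as far as 1 list per library shows. Peak names ran from 1 to the last peak with no number missing in 10 of 10 lists, and peaks overlapped each other in 0 of 10.

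A peak was called shared when a peak of the same target in the other condition overlapped it by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error within a list and not the spread between cultures. With 1 library per target and condition, no test of the treatment was made and no p-value refers to it. Losses at regions with a score of at least 500 were set against 10000 draws of matched regions. Those draws compare regions within the same libraries and do not cover the spread between cultures. The covered length of a list is the number of bases under its peaks. Overlap between targets within a condition was compared with 1000 circular shifts of the peaks within each chromosome, one-sided for more overlap, with Benjamini-Hochberg adjustment over 20 tests. This test describes the libraries and not the conditions. The smallest p it can give is 0.000999. The ends of chromosomes were taken as the highest peak end over all lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

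On simulated lists of 5000 peaks with 2000 planted shared peaks, the overlap step recovered 2000. The shift test called 7 of 100 pairs of unrelated lists at a p of at most 0.05. The simulated peaks of these pairs had equal widths and random places without clusters. The rate of false calls on clustered lists was therefore not measured.

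The comparisons, the alternatives and the rule for named regions were fixed before the data were examined. The rule names, for each target, the 3 highest-scoring regions of each condition with no peak of that target within 5 kb in the other condition, and the 3 highest-scoring of each list. The text prints part of them. Coordinates are 1-based on mm9. No annotation on mm9 was used here, and coordinates were not carried over to another build, so genes at the regions are not named. For that reason the planned counts of genes with a promoter peak, the promoter classes per gene and the 9 gene lists were not run. H3K4me3 peaks sorted by their overlap with H3K27me3 took the place of promoter classes, as planned.

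The following were chosen after the values were seen: the sorting of Pol II peaks by mark and score, domains joined over gaps of up to 3 kb, regions with a score of at least 500, hnRNP L clusters (at least 10 peaks chained over gaps of up to 100 kb), the H3K4me3 regions joined over both conditions, and windows of 100 kb and 1 Mb. Targets were first compared in windows of 100 kb by differences in kb, and the log2 ratio with 1 kb added was put first later, after both had been seen, because differences in kb grow with the length covered. The share of hnRNP L in clusters on placed chromosomes alone was also added then. Alternatives fixed in advance were an overlap of at least 50% of the shorter peak, a score of at least 100, equal numbers of top-scoring peaks, peaks within 1 kb merged, numbered chromosomes and X, and shifts of at most 1 Mb.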

Results

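The series holds 10 ChIP-seq peak lists from R1E mouse embryonic stem cells. It covers 5 targets, each in untreated cells and in cells given 0.5 uM Adriamycin, a DNA-breaking topoisomerase II poison, for 8 h. There was 1 library per target and condition, so differences between conditions have no replicate check. The lists held between 1022 peaks (hnRNP L, Adriamycin) and 97639 peaks (H3K27me3, untreated). Read depth was unknown, and the differences below are between deposited lists.

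The first comparison asked how much of the genome each target occupied in untreated and in Adriamycin-treated cells. Peaks covered less of the genome in the Adriamycin list for each of the 5 targets, and the largest differences were in Pol II and H3K27me3. Pol II peaks covered 77.4 Mb in untreated cells and 54.7 Mb after Adriamycin, and H3K27me3 peaks 101.0 Mb and 75.3 Mb. The differences were smaller for H3K4me3 (62.9 Mb and 57.6 Mb), H3K79me2 (138.9 Mb and 130.1 Mb) and hnRNP L (1.66 Mb and 1.62 Mb). For the histone marks and Pol II the covered length was lower on 20 of 20 chromosomes (the numbered ones and X), and for hnRNP L on 14 of 20. Chromosome X had the lowest ratio of Adriamycin to untreated for Pol II (0.594), H3K27me3 (0.707) and H3K79me2 (0.887).

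Numbers of peaks did not follow the covered length for 2 targets. H3K4me3 had 38421 peaks in untreated cells and 41705 after Adriamycin, and H3K79me2 had 63053 and 71959. Pol II had 81069 and 59426 peaks, H3K27me3 97639 and 88365, and hnRNP L 1120 and 1022. Peaks that matched 1 to 1 between conditions were narrower after Adriamycin. The median difference was -123 bp for H3K27me3, -90 bp for H3K4me3, -84 bp for H3K79me2, -58 bp for Pol II and -21.5 bp for hnRNP L.

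**Figure D1:**
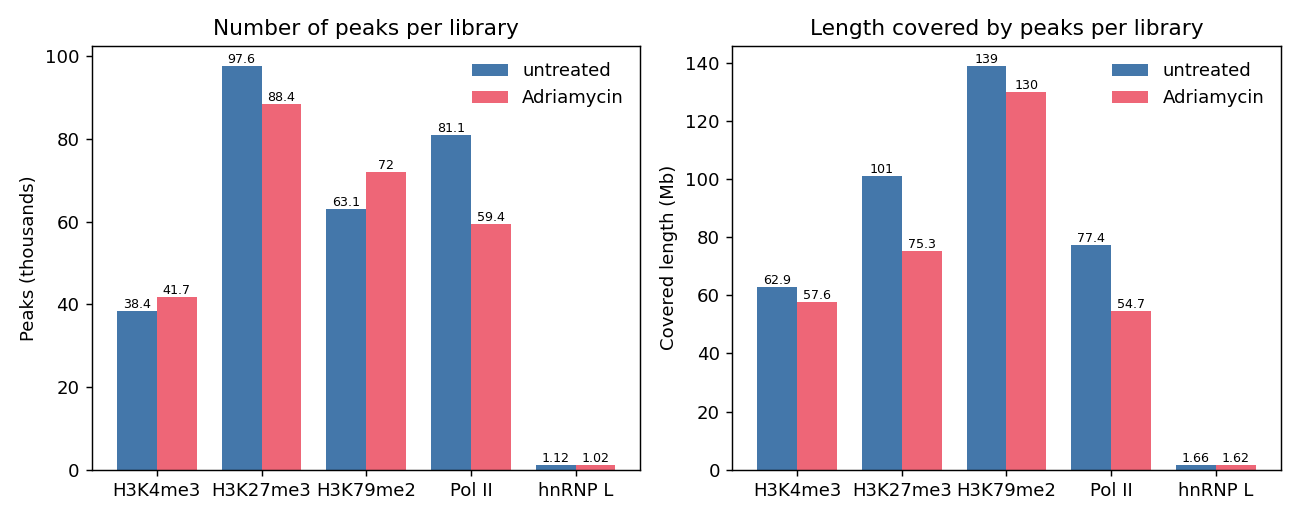
Bars give the number of peaks, in units of 1000 (left), and the length covered by peaks in Mb (right), for each target, with 1 library per bar and no error bars. Covered length was lower after Adriamycin for each target, from 77.4 to 54.7 Mb for Pol II.

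The second comparison asked which peaks were found in both conditions. By share of peaks H3K4me3 was the most alike, with 85.5% of untreated peaks (interval 85.2 to 85.9%) and 84.2% of Adriamycin peaks (83.8 to 84.5%) shared. H3K79me2 followed with 81.0% and 82.0%. Pol II had the lowest share in the untreated list, with 52.0% of untreated peaks (51.7 to 52.4%) but 73.9% of Adriamycin peaks (73.6 to 74.3%) shared. In the full lists 38905 untreated and 15500 Adriamycin Pol II peaks had no partner. With equal numbers of top-scoring peaks they were 22092 and 19736. H3K27me3 had 58.8% and 73.0% (33297 and 26005 unpartnered peaks at equal list length, against 40237 and 23863), and hnRNP L 63.9% (61.0 to 66.7%) and 69.6% (66.6 to 72.4%), the lowest share in the Adriamycin list. By covered bases the order of the first 2 turned. The bases covered in both conditions were 75.7% of those covered in either for H3K79me2, 71.0% for H3K4me3, 53.1% for hnRNP L, 50.5% for H3K27me3 and 45.3% for Pol II.

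Peaks without a partner were mostly weak. When untreated Pol II peaks were ranked by score and cut into 10 equal parts, 80.7% of the lowest part had no partner, against 0.925% of the highest. For H3K27me3 these shares were 74.6% and 0.717%. Pol II had 38905 untreated peaks without a partner, and 13933 when peaks with a score of at least 100 were held against any Adriamycin peak.

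**Figure D2:**
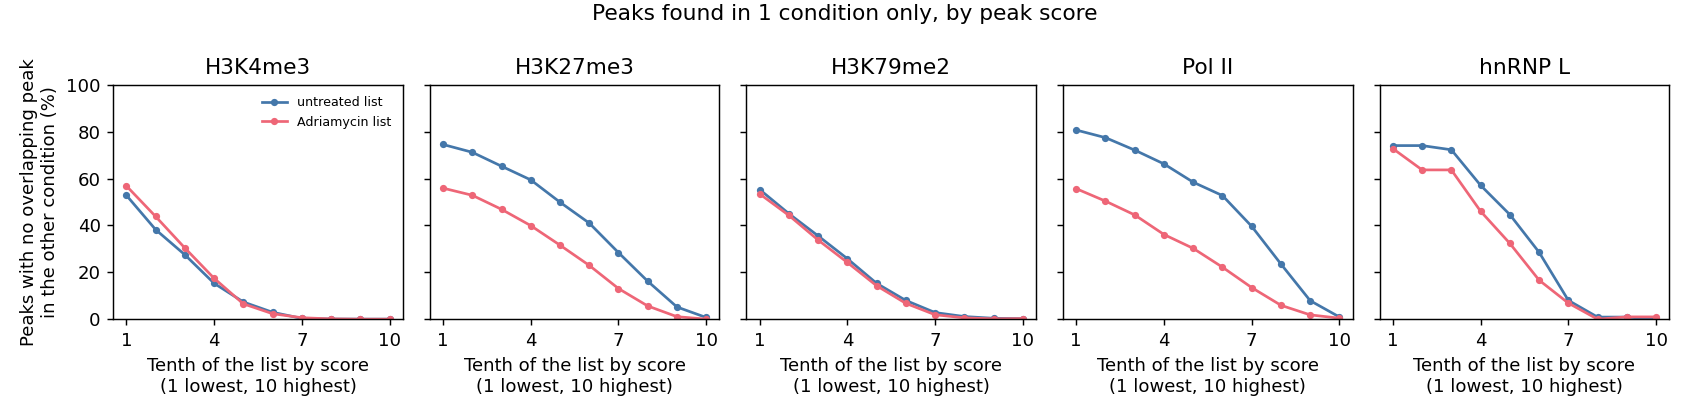
Each panel shows 1 target, with 10 equal parts of the list by peak score on the x axis (1 lowest, 10 highest) and the percent of its peaks with no overlapping peak in the other condition on the y axis. For Pol II the untreated line starts at 80.7% and ends at 0.925%.

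For H3K4me3, 5558 untreated peaks and 6596 Adriamycin peaks had no partner, and 2664 and 4222 lay over 5 kb from any peak of the other list. Among peaks with a score of at least 100 held against any peak, 1865 and 1968 had no partner. The strongest such untreated regions were on chromosome 11 at 69692486-69695754 (score 2058.95), chromosome 4 at 125403642-125407735 (score 1845.75) and chromosome 10 at 21546249-21551445 (score 1512.16). Each held a Pol II peak in untreated cells and none after Adriamycin. H3K79me2 did not follow Pol II there. It was absent in both conditions on chromosome 11, present in both on chromosome 4, and present only after Adriamycin on chromosome 10. The strongest Adriamycin regions were on chromosome 1 at 137661727-137668488, with Pol II and H3K79me2 in both conditions, and chromosome 5 at 143189772-143195099 and chromosome 17 at 33011936-33016464, each with Pol II in untreated cells and none after treatment. With equal numbers of top-scoring peaks the untreated list had more unpartnered H3K4me3 peaks, by 1917 (a difference of -1917).

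For H3K27me3, 40237 untreated peaks and 23863 Adriamycin peaks had no partner. At a score of at least 500, 17 untreated regions and 0 Adriamycin regions lay over 5 kb from any peak of the other list. The strongest untreated regions were on chromosome 1 at 92893242-92899170 (score 1551.39), chromosome 5 at 32518366-32520699 (score 1429.67) and chromosome 6 at 91752844-91760589 (score 969). These 3 regions held H3K4me3 in both conditions and no H3K79me2 in either. The one on chromosome 5 held a Pol II peak after Adriamycin and none before. Among all 17 untreated regions, 8 held H3K4me3 before and 8 after Adriamycin, and 2 held H3K79me2 before and 2 after. The strongest Adriamycin region, on chromosome 4 at 152794021-152799139, had a score of 360.09.

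H3K27me3 peaks also formed long domains when joined over gaps of up to 3 kb. Domains of at least 20 kb numbered 887 in untreated cells and 632 after Adriamycin, those of at least 50 kb 68 and 49, and those of at least 100 kb 10 and 2. The longest untreated domain spanned 137.953 kb on chromosome 15 at 102735147-102873099, where the longest Adriamycin domain was 95.627 kb. The domain on chromosome 11 at 96116400-96248468 spanned 132.069 kb, against 92.758 kb. Each of these places held 2 domains in the Adriamycin list, so the untreated domain was split there. Peaks numbered 57 in untreated cells and 77 after Adriamycin on chromosome 15, and 41 and 55 on chromosome 11. The domain on chromosome 2 at 74481418-74609008 was 127.591 kb in untreated cells and 127.767 kb after Adriamycin. Within the chromosome 15 domain, peaks covered 85.8% of the bases in untreated cells and 69.4% after treatment.

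For H3K79me2, unpartnered peaks were nearly even, with 11959 in untreated cells and 12931 after Adriamycin. That order turned under 4 of the alternatives, so no direction is given. The strongest Adriamycin regions were on chromosome 8 at 125433509-125478801, chromosome 7 at 140195699-140235290 and chromosome 2 at 24754449-24775163. Each held Pol II in both conditions. The strongest untreated regions were on chromosome 4 at 34808518-34810097 and chromosome 8 at 127364568-127370073, where a Pol II peak was also found before but not after treatment, and chromosome 7 at 108061710-108080434, where Pol II was found in both. The longest H3K79me2 domain spanned 211.6 kb on chromosome 11 at 107121777-107333376 and 236.775 kb after treatment. Peaks covered 86.9% of that longer span in untreated cells and 86.7% after Adriamycin, and it held 4 untreated domains. Long H3K79me2 domains were fewer after treatment. Those of at least 20 kb numbered 2609 in untreated cells and 2519 after Adriamycin, those of at least 50 kb 499 and 444, and those of at least 100 kb 60 and 45.

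For Pol II, 184 untreated regions and 12 Adriamycin regions with a score of at least 500 lay over 5 kb from any peak of the other list. Of the 184, 144 held H3K4me3 in untreated cells and 113 after Adriamycin. The strongest were on chromosome 11 at 117791773-117798080 (score 2549.35), chromosome 6 at 145121988-145128610 (score 2211.53) and chromosome 12 at 81891069-81891996 (score 2145.9), and each kept an H3K4me3 peak. Of the 144, 31 had no H3K4me3 peak after Adriamycin, above the highest of 10000 matched draws (20, mean 9.89). The strongest Adriamycin regions were on chromosome 9 at 103362069-103373209 (score 1939.83) and chromosome 8 at 119552209-119571577 (score 1037.36). Both held H3K27me3 in both conditions and no H3K79me2 in either. The third, on chromosome 6 at 90548817-90551434 (score 786.15), held H3K27me3 after Adriamycin and not before. Of the 12 regions, 6 held H3K27me3 after Adriamycin and 5 in untreated cells.

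Pol II peaks differed by the marks they overlapped. Untreated peaks without a partner made up 30.5% of those at H3K4me3, 55.9% of those at H3K79me2 without H3K4me3, 49.5% of those at H3K27me3 without the other marks, and 59.8% of those at none of the 3 marks. At scores of 100 to 200, the shares were 53.5%, 52.3%, 34.0% (interval 31.0 to 37.2%) and 53.8% in that order. Pol II peaks at H3K27me3 without the other marks thus had a partner more often than peaks of like score elsewhere, and among those of at most 500 bp the shares were 38.1% there and 56.3% at H3K4me3. Among Adriamycin Pol II peaks of score 100 to 200, 37.9% at H3K27me3 had no untreated partner (34.5 to 41.5%), 24.2% at none of the 3 marks (22.9 to 25.4%), 14.9% at H3K79me2 (13.7 to 16.1%) and 8.71% at H3K4me3 (7.91 to 9.56%).

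Many hnRNP L peaks lay close together. In untreated cells 462 of 1120 peaks (41.2%, interval 38.3 to 44.2%) lay in 15 clusters that span 4.16 Mb, and after Adriamycin 450 of 1022 (44.0%, 41.0 to 47.1%) lay in 15 clusters of 4.38 Mb. The largest untreated clusters were on chromosome 4 at 144994067-146234629 with 96 peaks and chromosome 5 at 14910333-15220428 with 67 peaks. Next came chromosome 4 at 146343191-146827722 with 56 peaks and chromosome 8 at 71942414-72111104 with 38 peaks. Unplaced contigs held 158 untreated peaks (14.1%) and 153 Adriamycin peaks (15.0%) of hnRNP L. The 8 lists of the other targets held 0 peaks there, and whether those lists were made with these contigs is not given in the sources used here, so the targets are not compared on them. Clustered peaks were shared as often in both lists (70.3% of untreated and 70.7% of Adriamycin peaks), and peaks outside clusters and contigs were shared in 58.5% and 68.1%. The strongest hnRNP L region of 1 condition was on chromosome 2 at 98506231-98508000 in the Adriamycin list (score 1958.01), with no peak of the other targets. Whether sequence present in many copies lies there was not checked, so a mapping artifact is not excluded.

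**Figure D3:**
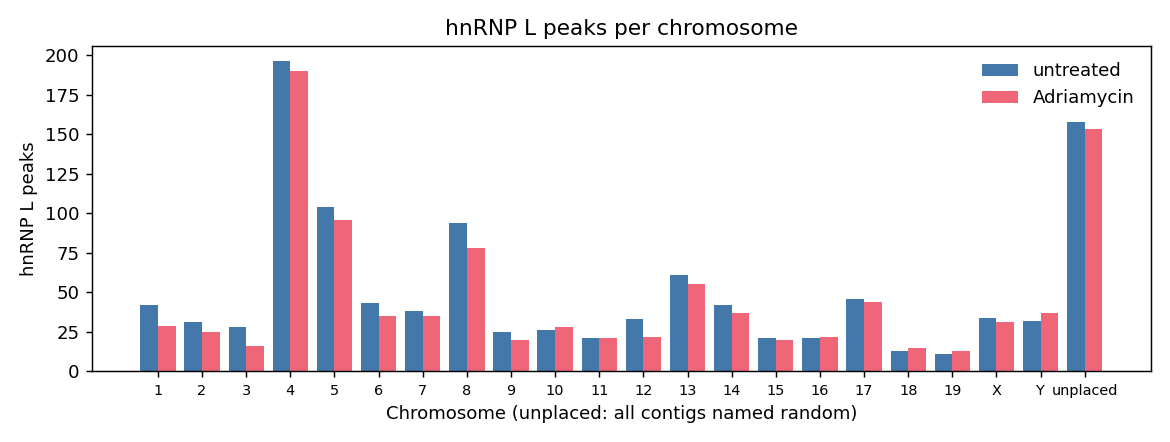
Bars give the number of hnRNP L peaks per chromosome in the untreated and the Adriamycin list, 1 library each, with unplaced contigs pooled in the last pair. The unplaced contigs held 158 and 153 peaks.

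The third comparison asked how promoter-type H3K4me3 peaks were combined with the other targets. H3K4me3 together with H3K27me3 marks bivalent promoters of embryonic stem cells. H3K27me3 overlapped 28.1% of H3K4me3 peaks in untreated cells (27.6 to 28.5%) and 23.5% after Adriamycin (23.1 to 23.9%). H3K79me2 overlapped 38.4% and 33.9%, and Pol II 61.3% (60.8 to 61.8%) and 49.6% (49.1 to 50.1%). H3K4me3 peaks with none of the 3 were 16.5% and 26.6%. Overlap of shifted H3K4me3 peaks was lower after Adriamycin too, at 8.48% and 6.48% for H3K27me3 and 6.95% and 4.92% for Pol II. Relative to shifted peaks, overlap was higher after Adriamycin for H3K27me3 (ratios 3.31 and 3.63) and Pol II (8.82 and 10.1). It was lower for H3K79me2 (4.99 and 4.69). The lower shares alone therefore do not show a loss of H3K27me3 or Pol II from H3K4me3 peaks. Nor do the higher ratios alone show closer overlap, since ratios also rose with stricter lists. With a score of at least 100, the untreated ratios were 4.92 for H3K27me3 and 11.8 for Pol II.

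Within the 34584 H3K4me3 regions found in both conditions, losses outnumbered gains for each target. Pol II was found at 22644 regions in untreated cells and 19284 after Adriamycin. It was absent after treatment from 4476 (19.8%, 19.2 to 20.3%), and it appeared at 1116 of the 11940 regions without it (9.35%, 8.83 to 9.88%). H3K27me3 was absent after treatment from 1903 of 10401 regions (18.3%) and appeared at 526 of 24183 (2.18%). H3K79me2 was absent from 1251 of 13892 (9.01%) and appeared at 622 of 20692 (3.01%). Pol II was absent after treatment from 12.8% of its regions with H3K79me2 and no H3K27me3, from 28.4% of those with H3K27me3 and no H3K79me2, and from 28.1% of those with neither. These shares were not matched on Pol II score, so they do not separate the marks from peak strength. Untreated Pol II peaks at H3K4me3 had no partner in 71.3% at scores of 50 to 100 and in 0.945% at 1000 and above. Pol II appeared at 76 of the 831 regions without it that lost H3K27me3 (9.15%, 7.27 to 11.3%) and at 536 of the 4856 that kept H3K27me3, a share within that interval.

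The fourth comparison asked which targets lay together within a condition. H3K4me3 peaks overlapped Pol II 8.82 times as often as shifted peaks in untreated cells and 10.1 times after Adriamycin. The ratios were 4.99 and 4.69 for H3K4me3 with H3K79me2, 5.04 and 4.84 for H3K79me2 with Pol II, and 3.31 and 3.63 for H3K4me3 with H3K27me3. Each of these had an adjusted p of 0.002 after Benjamini-Hochberg correction, from the smallest p the shifts can give. Against shifts of at most 1 Mb these ratios were lower, at 4.10 and 4.53 for H3K4me3 with Pol II, 2.54 and 2.40 for H3K4me3 with H3K79me2, 2.52 and 2.36 for H3K79me2 with Pol II, and 2.02 and 2.13 for H3K4me3 with H3K27me3, each past the threshold (adjusted p 0.0165). H3K79me2 and H3K27me3 avoided each other, with ratios of 0.331 and 0.307, and fewer overlaps than in any of 1000 shifts. Pol II with H3K27me3 gave 1.43 and 1.96 (adjusted p 0.002), but against shifts of at most 1 Mb 0.812 and 1.04.

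hnRNP L peaks overlapped Pol II 2.04 times as often as shifted peaks in untreated cells (adjusted p 0.0183) and 2.06 times after Adriamycin (adjusted p 0.0214). They overlapped H3K27me3 1.91 times (adjusted p 0.0183) and 1.99 times as often (adjusted p 0.02). Overlap with H3K4me3 had ratios of 1.05 and 0.957, and with H3K79me2 1.00 and 1.06, and none of these passed the threshold of 0.05. With peaks of a score of at least 100 (614 and 578 peaks, 100 shifts), the ratios were 1.72 and 1.90 for Pol II (adjusted p 0.0762 and 0.054) and 1.797 and 1.718 for H3K27me3 (adjusted p 0.0762 and 0.113), and no longer passed it. Outside clusters and contigs, hnRNP L overlapped Pol II at 82 of 588 untreated peaks (13.9%, ratio 2.70) and 67 of 505 Adriamycin peaks (13.3%, ratio 3.14). They overlapped H3K27me3 at more, 110 (18.7%, ratio 2.81) and 83 (16.4%, ratio 2.87), and each of these 4 ratios had an adjusted p of 0.002.

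**Figure D4:**
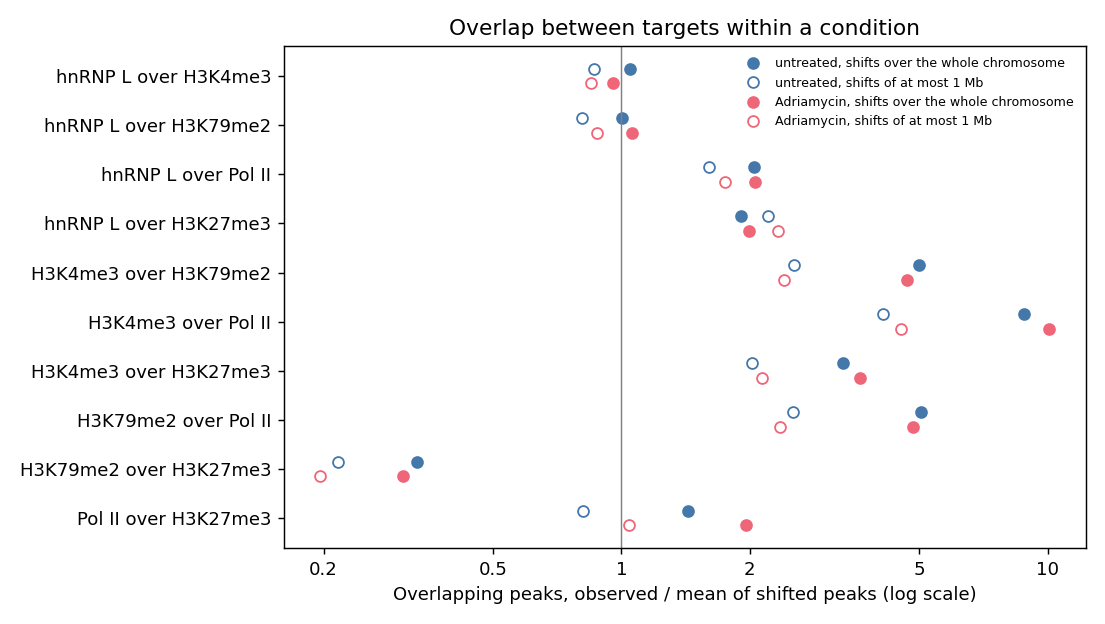
Points give overlapping peaks as the ratio of observed to the mean of shifted peaks on a log axis, for 10 pairs of targets in untreated (blue) and Adriamycin (red) libraries. Filled points are shifts over the whole chromosome and open points shifts of at most 1 Mb, and the Pol II and H3K27me3 pair in untreated cells lies at 1.43 and 0.812.

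In windows of 100 kb, the log2 ratio of Adriamycin to untreated covered length (with 1 kb added to each) of Pol II went with that of H3K4me3, with Pearson's r of 0.548 over 3273 windows with at least 5 kb of both in untreated cells. It went less with that of H3K79me2 (r 0.214 over 3687 such windows) and was weakly negative against H3K27me3 (r -0.101 over 1805 windows). On differences in kb in the same windows, used first, r was 0.512, 0.240 and -0.233 in that order. In the last set of windows the median log2 ratios were below 0 for both, at -0.32 for H3K27me3 and -0.46 for Pol II. Windows are neighbours along chromosomes and not independent, so no p-value is given. The window on chromosome 2 at 35500001-35600000 went from 11.2 to 77.6 kb of H3K79me2, from 17.1 to 36.7 kb of Pol II and from 7.94 to 20.1 kb of H3K4me3. In the Adriamycin list 1 H3K79me2 peak, at 35516908-35570426 (score 2414.55), made up most of the H3K79me2 length. The untreated list held no H3K79me2 peak between 35516615 and 35575124. Untreated Pol II and H3K4me3 peaks lay in that stretch, so an omission by the peak caller was not excluded. On chromosome 1 at 191600001-191700000, Pol II went from 4.02 to 45.7 kb and H3K79me2 from 13.1 to 39.2 kb. On chromosome 12 at 17700001-17800000, Pol II went from 1.31 to 27.4 kb and H3K79me2 from 37.8 to 74.0 kb. At least 10 kb of H3K79me2 and of Pol II was gained at 7 windows and lost at 30, among them chromosome 1 at 120800001-120900000, where Pol II went from 24.8 to 1.75 kb. Losses outnumbered gains for each target alone too. Of 19323 windows, 129 gained and 655 lost at least 5 kb of H3K79me2, and 191 gained and 1773 lost that much Pol II. The windows named here were chosen after their values were seen.

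**Figure D5:**
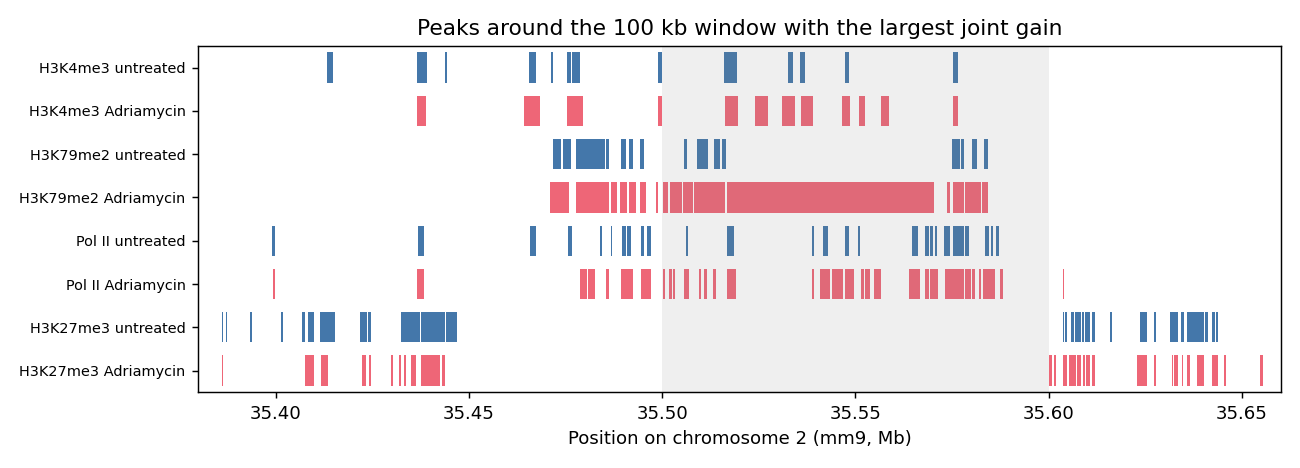
Boxes are peaks of 4 targets in untreated (blue) and Adriamycin (red) cells along chromosome 2 on mm9, in Mb, with the window at 35500001-35600000 shaded. In the shaded window H3K79me2 covered 11.2 kb in untreated cells and 77.6 kb after Adriamycin.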

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

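Most of the overlaps between targets kept their direction and their side of the threshold, and the counts of unpartnered peaks depended on the score. Of 68 ratios between targets under an alternative, 52 did so. Of 72 counts of peaks found in 1 list, 35 stayed within 1.5 times the value reported. The list with more unpartnered peaks was the same in 30 of 36 comparisons. Holding peaks within 5 kb as shared and leaving out hnRNP L clusters with unplaced contigs were chosen after seeing the data. The cause was not tested for the changes below, apart from stricter settings leaving fewer peaks. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. The alternatives for promoters and gene lists were not run, since no annotation on mm9 was used here. Unknown read depth limits each comparison of weak peaks.

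Unpartnered counts are given as untreated and then Adriamycin. With a score of at least 100 in both lists they were 18358 and 7152 for H3K27me3, 6964 and 6693 for H3K79me2, 22825 and 4908 for Pol II and 134 and 103 for hnRNP L, and 4246 for Adriamycin H3K4me3. With that score in the counted list and any in the other they were 1865 and 1968 for H3K4me3, 8229 and 2590 for H3K27me3, 2773 and 2599 for H3K79me2, 13933 and 2694 for Pol II, and 71 and 49 for hnRNP L. With no peak within 5 kb they were 2664 and 4222, 14766 and 7225, 2024 and 2025, 15082 and 6383, and 268 and 180 in the same order of targets. With peaks within 1 kb merged, untreated H3K27me3 had 26264, H3K79me2 5800 and 5714, and untreated Pol II 22744. With equal numbers of top-scoring peaks, Adriamycin H3K79me2 had 8279 and untreated Pol II 22092. Without clusters and contigs hnRNP L had 244 and 161.

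The difference of Adriamycin minus untreated unpartnered peaks changed sign to -1917 for H3K4me3 and -6339 for H3K79me2 with equal numbers of top-scoring peaks, and to 3 for hnRNP L. For H3K79me2 it was also -271 with a score of at least 100 in both lists, -86 with peaks merged and -174 with that score in the counted list.

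With peaks of a score of at least 100, the hnRNP L ratios lost their call at 1.72 and 1.903 for Pol II and 1.797 and 1.718 for H3K27me3, and fell below 1 at 0.78 for H3K4me3 in untreated cells and 0.6951 and 0.6996 for H3K79me2. Against shifts of at most 1 Mb, Pol II with H3K27me3 went to 0.8122 in untreated cells and lost its call at 1.045 after Adriamycin, and hnRNP L went to 0.8601 for H3K4me3 in untreated cells and to 0.8093 and 0.8743 for H3K79me2. At an overlap of 50%, untreated hnRNP L with H3K79me2 was 0.9484. Without clusters and contigs, hnRNP L was 0.6839 for H3K4me3 in untreated cells and 0.8067 and 0.5916 for H3K79me2. The share of H3K4me3 peaks at H3K27me3 was 26.74% and 22.02% with a score of at least 100.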

Other observations

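The tests in this part were chosen after the results were seen. One window of 1 Mb out of 795 with at least 20 kb of each histone mark and Pol II in untreated cells ranked in the top 5% of covered length ratio for all 4 of them. It lay on chromosome 4 at 153000001-154000000. The ratios of Adriamycin to untreated were 1.21 for H3K4me3, 1.15 for H3K27me3, 1.32 for H3K79me2 and 1.72 for Pol II. The medians over the 795 windows were 0.922, 0.750, 0.931 and 0.698. Pol II covered 68.8 kb there in untreated cells and 118.5 kb after Adriamycin.

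Covered length was lower in the Adriamycin list of each target, which could come from lower sensitivity of the treated libraries. For H3K4me3 this stays open, since 4222 Adriamycin peaks and 2664 untreated peaks stood over 5 kb from the other list, but 1968 and 1865 had no partner at a score of at least 100, and the order turned at equal list length (a difference of -1917 unpartnered peaks). For Pol II, losses from the untreated list at like score were close at H3K4me3, at H3K79me2 and at none of the 3 marks. They differed by at most 4.03 percentage points, as lower sensitivity would give. In the Adriamycin list at scores of 100 to 200, the shares without a partner were 8.71%, 14.9% and 24.2% in that order. These 3 groups thus did not behave alike in both lists, and the cause is not settled for them. Pol II peaks at H3K27me3 without H3K4me3 or H3K79me2 were lost less, at 34.0% for scores of 100 to 200 against a lowest bound of 51.06% elsewhere, which uniform loss of sensitivity would not give, while at H3K4me3 regions, not matched on score, Pol II was lost more with H3K27me3 (24.1%) than without (18.6%). Narrower 1-to-1 peaks accounted for 18.0% of the lost length for Pol II, 31.7% for H3K27me3, 38.3% for hnRNP L, 43.7% for H3K79me2 and 64.0% for H3K4me3, and a response to Adriamycin remains open as a hypothesis because depth is unknown and each condition has 1 library.

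Strong regions with no counterpart within 5 kb may be omissions by the peak caller or differences between the cultures. For H3K79me2 this stays open. Of the 7 strong Adriamycin regions, 6 held Pol II in untreated cells, but few losses were to be found in any case. Each draw of matched regions held 0.207 regions that lacked Pol II in untreated cells, on average. Of the 3 strong untreated regions, 2 lost Pol II. Of the 23 strong H3K4me3 regions found in untreated cells, 17 held Pol II there and 15 of these lacked it after Adriamycin, above the highest of 10000 draws of matched H3K4me3 regions (11), and in the mirror case 8 of the 13 Adriamycin regions with Pol II lacked it in untreated cells, also above the highest draw (5), while 6 others of the 32 had Pol II in untreated cells and not after. Omission from the H3K4me3 list alone would not remove Pol II from the same places. Of the 23 regions, 11 held a peak of another target after Adriamycin. Such a peak shows DNA at the part it overlaps, in the cells of another library. Loss of part of these regions, or loss in some cells, is therefore not excluded. At the other 12 loss of the DNA stays open altogether, although 19 of the 23 had such a peak within 5 kb. An omission shared by the H3K4me3 and Pol II lists also stays open, since use of an input library is unknown. A difference in activity at these regions, in either direction, and a difference between cultures stay open and were not tested.

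The grouping of hnRNP L peaks may come from multi-copy sequence, where reads from many copies pile up on few places. On placed chromosomes the share in clusters was 38.9% in untreated cells (374 of 962 peaks), against 0 in each of 1000 Pol II lists thinned to the same number of peaks, which measures the clustering and does not favour a source of it, and the genome sequence was not analysed here. The peaks elsewhere were not placed without regard to Pol II. They overlapped it 1.97 times as often as peaks shifted by at most 1 Mb, and the 82 overlaps were above the highest shift of 64. They overlapped H3K27me3 more still (2.46 times by the same shifts), and H3K4me3 (0.529) and H3K79me2 (0.651) less than shifted peaks, which does not point to transcribed gene bodies or active promoters, and the source of the Pol II overlap stays open.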
